A study of Homo sapiens with 4 samples.

How the data were processed

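Libraries were made by the submitters from total RNA of the grafts, with an amplifying, stranded kit for very small amounts of RNA, and sequenced as single reads, per the labels' protocols. The deposited table holds raw read counts per Ensembl gene, 1 column per library. Per the submitters' processing notes, the tools were bcl2fastq 2.17.1.14, cutadapt 1.9.1, STAR and HTSeq, with the hg38 build. The annotation release, the strand setting of the counting and any mapping to the chicken genome are not given in the sources used here, so overlapping and antisense genes may share reads, and chicken reads similar to human sequence may have been counted. Amplified reads carried no stated molecular identifiers, so the floors cover counting error only.

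The 4 libraries were assigned to control and gemcitabine with carboplatin by their labels, 2 to each. Of the 60676 gene rows, 60357 had a symbol in a table of gene names and 58503 were found in GENCODE release 29 (GRCh38, the assembly the notes name as hg38), which supplied gene types, positions, GC content and transcript length. In 30591 rows no library had a count. Totals ran from 30278292 to 84264150 counts, and genes with at least 1 count numbered 21650, 23384, 24670 and 22803 in controls 1 and 2 and treated libraries 1 and 2.

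Genes were filtered with filterByExpr, scaled by TMM (factors 0.991 to 1.01) and compared with the quasi-likelihood F-test of edgeR 4.0.16 (robust, without a block) in R 4.3.3. P-values were adjusted by Benjamini-Hochberg over the 19161 genes kept, with a threshold of 0.05. The design named the version 4 default of the quasi-likelihood fit, with the earlier method as the alternative. The installed package defaults to the earlier method, so the newer one was set by hand. The earlier method also called 0 genes (550 higher and 733 lower at an unadjusted p under 0.05, smallest adjusted p = 0.298). The fit had 2 residual degrees of freedom and a median of 5.65 prior ones, and the median biological coefficient of variation was 0.272. Fold changes are treated over control, and standard errors are the size of the fold change over the root of F. CPM used TMM-scaled totals and are given as mean ± SD.

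Before the data were examined, 40 gene lists were fixed: 30 biological programs, 7 sets of markers of other cell types and 3 sets on RNA quality. The 39 with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, in 1 Benjamini-Hochberg family, and list medians have bootstrap intervals over genes from 10000 draws, which treat genes as independent. The test with the correlation estimated from the data and fry, which asks whether the genes of a list move on balance one way, served as alternatives. Each list was also adjusted alone.

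Genes were named by a rule fixed at the same time. It took the 12 genes per direction with the smallest adjusted p past the threshold, with a symbol and with groups that did not overlap. With fewer than 5 passing, the 5 smallest unadjusted p were taken, as values that did not pass. The rule also took the 3 members with the smallest p in the list's direction for each called list, 17 fixed genes of drug handling, proliferation and the p53 response, and for other cell types the 2 members with the highest mean CPM. A few genes that the rule took are not reported here. They stayed in every test, list and count.

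Alternatives fixed beforehand were RLE and upper quartile scaling, no count filter, a mean of at least 50 counts, DESeq2 1.42.0, limma-voom, the earlier quasi-likelihood method, the replicate number as a block, leaving out each library, leaving out mitochondrial and structural RNA genes, and thinning to 30278292 counts. Offsets for GC content and transcript length, fitted per library, and a mean of at least 500 counts were added after seeing the data. GC content and length were found for 98.8% of tested genes. Where a group was left with 1 library, that library was assumed to vary like the other group.

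The steps were tested on simulated data, with counts drawn for the real genes from the means, dispersions and totals of the 4 libraries and 200 genes changed by known folds, of which 17566 genes passed the filter. For this comparison the edgeR test recovered 1.49%, 14.9% and 54.5% of genes changed 1.5, 2 and 4-fold and called 1 of 17381 unchanged genes. DESeq2, run on all simulated genes without that filter, recovered 13.4%, 32.8% and 59.1% and called 62 unchanged genes. A list of 40 genes raised by 0.4 on the log2 scale was called by camera with the preset correlation (adjusted p = 4.07e-05), and 0 of 39 unshifted lists were. The raised list was missed with an estimated correlation (adjusted p = 0.965) and by fry (adjusted p = 0.432). Simulated genes were drawn independently of each other, so these draws could not test whether the preset correlation was too low for the real lists. In the real libraries the estimate lay above the preset for several lists, and camera also called lists in splits that mixed the groups. Plots were drawn with matplotlib 3.10.9.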

Results

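Bulk RNA-seq was done on tumours grown from MDA-MB-436, an established human triple-negative breast cancer cell line, after its cells had been grafted into chicken embryos. Embryos received either saline, the control, or a mixture of gemcitabine and carboplatin into the bloodstream. Gemcitabine is a deoxycytidine analogue that blocks DNA synthesis and ribonucleotide reductase, and carboplatin is a platinum compound that crosslinks DNA. Each condition had 2 libraries, and the deposited table gave raw counts for 60676 genes. The controls held 84264150 and 41628181 counts, and the treated libraries held 55011800 and 30278292. A single library could therefore show a gene only above a floor of 3 counts, which was 0.0356 and 0.0721 CPM (counts scaled to library size) in controls 1 and 2 and 0.0545 and 0.0991 CPM in treated libraries 1 and 2. The comparison asked which human transcripts differed between treated and control grafts. The sources used here call the libraries duplicates and do not say whether they came from separate embryos or cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Those of camera at its preset correlation compare the genes of a list with all other genes. They rest on the spread across genes and do not measure how far libraries of a group differ.

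After gemcitabine and carboplatin, genes of S phase and of homologous recombination repair rose as groups, while replication-dependent histone genes, G2/M genes and mesenchymal and matrix genes fell as groups. Of these lists, only those of histone and G2/M genes were also called in a comparison that mixed treated and control libraries. S-phase genes, which encode replication and nucleotide synthesis factors, had a median log2 fold change of 0.40 over 44 members (95% bootstrap interval over genes 0.34 to 0.49), with 43 of the 44 above 0. Histone genes had a median of -0.39 over 50 members, and mesenchymal and matrix genes had a median of -0.39 over 34. In all, camera with its preset correlation called 5 of 39 lists higher and 10 lower at a Benjamini-Hochberg adjusted p under 0.05. With an estimated correlation it called 0 lists (smallest adjusted p = 0.547), and fry called 0 (smallest adjusted p = 0.101), so each call below rests on the preset correlation. Against the preset 0.01, the estimate was 0.16 for S-phase, 0.42 for histone, 0.40 for G2/M and 0.75 for hypoxia genes. It was 0.0073 for matrix and for homologous recombination genes and -0.015 for NF-kB genes. Where the estimate lay above the preset, the preset adjusted p is too small to the extent that the estimate holds. In the splits that mixed treated and control libraries on each side, camera at the preset correlation called 6 and 2 lists. Its adjusted p can therefore pass the threshold on differences between libraries of the same group. The higher lists numbered 3 without control 1, and the lower lists numbered 4 without control 2 and 5 without treated 1. Both treated libraries lay on the list's side of both controls in 39 of 44 S-phase, 17 of 35 homologous recombination, 11 of 24 gemcitabine, 3 of 12 structural RNA and 3 of 13 mitochondrial members. For the lower lists the counts were 27 of 50 histone, 27 of 56 G2/M, 19 of 34 matrix, 13 of 21 immediate early, 11 of 32 hypoxia and 10 of 19 glycolysis members. They were 9 of 26 NF-kB, 8 of 16 antigen presentation, 5 of 13 stem-like and 10 of 40 interferon-stimulated members. Chance separates the groups in 33.3% of genes, both directions together, and up to 4 members of a list separated the other way.

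**Figure D1:**
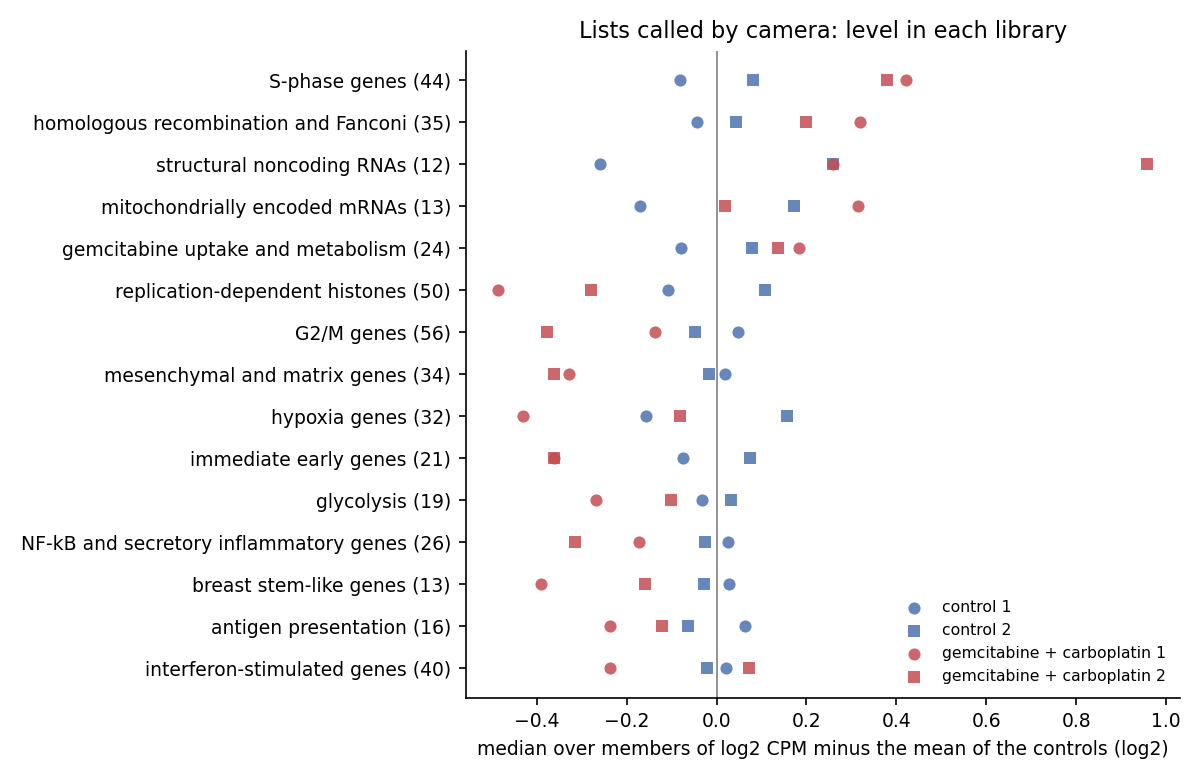
Level of each list called by camera in the 4 libraries, given as the median over its members of log2 CPM minus the mean of the controls, with the number of members tested in brackets and each library as a point. S-phase genes stand at 0.42 and 0.38 in the treated libraries against -0.08 and 0.08 in the controls, and interferon-stimulated genes stand at -0.24 and 0.07 in the treated libraries.

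The S-phase list rose with a camera adjusted p of 3.03e-26 (adjusted p = 0.547 with an estimated correlation). Of its 44 members, 19 were higher when adjusted over the list alone. Over all genes edgeR called 0 of them, against 26 at an unadjusted p under 0.05, 6 by DESeq2 and 0 by limma-voom. CLSPN, which encodes the checkpoint adaptor claspin, had 265 ± 6.09 CPM in the controls and 422 ± 28.0 CPM in the treated libraries (mean ± SD, n = 2 each), a log2 fold change of 0.68 (SE 0.11). The exonuclease gene EXO1 had 64.3 ± 16.1 and 131 ± 11.1 CPM, a log2 fold change of 1.05 (SE 0.19). RRM2, which encodes a subunit of ribonucleotide reductase, had a log2 fold change of 0.61 (SE 0.12), and the sliding clamp gene PCNA had one of 0.59 (SE 0.19), with 0.30 without control 1 and 0.89 without control 2. The list of homologous recombination and Fanconi genes, which repair double-strand breaks and crosslinks, rose by a median of 0.27 over 35 members (camera adjusted p = 1.58e-05; adjusted p = 0.547 with an estimated correlation). Of these, 27 were above 0, and 2 were higher when adjusted over the list alone. Adjusted over all genes, edgeR called 0 of them, against 9 higher and 1 lower at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. FANCB, which encodes a subunit of the Fanconi core complex, had a log2 fold change of 0.96 (SE 0.25). This list shares 4 members with the S-phase list, and its other 31 members had a median of 0.17 (95% bootstrap interval 0.12 to 0.34).

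Replication-dependent histone genes, which are transcribed in S phase and mostly lack poly(A) tails, fell with a camera adjusted p of 5.06e-20 (adjusted p = 0.562 with an estimated correlation). Of the 50 tested, 46 were below 0 and 20 were lower when adjusted over the list alone. With all genes counted, edgeR called 0 of them, against 23 at an unadjusted p under 0.05, 8 by DESeq2 and 0 by limma-voom. The linker histone gene H1-1 had 46.8 ± 1.43 CPM in the controls and 18.7 ± 4.52 CPM in the treated libraries (log2 fold change -1.37, SE 0.22). H1-4 had a log2 fold change of -0.77 (SE 0.14) and H2AC6 one of -0.70 (SE 0.13). Many histone genes have similar sequences, so reads that match several of them may have been left out or assigned to the wrong gene in counting. G2/M genes, which act in mitotic entry and chromosome segregation, fell by a median of 0.24 over 56 members (camera adjusted p = 3.69e-11; adjusted p = 0.630 with an estimated correlation). Here 50 members were below 0, and 0 passed when adjusted over the list alone or over all genes by edgeR, while 13 were lower and 1 higher at an unadjusted p under 0.05 and DESeq2 called 2 lower and limma-voom 0. The mitotic kinase gene PLK1 had a log2 fold change of -0.84 (SE 0.24), the ubiquitin-conjugating enzyme gene UBE2C one of -0.68 (SE 0.14) and the centromere chaperone gene HJURP one of -0.39 (SE 0.12). The proliferation marker MKI67 had 304 ± 15.2 and 288 ± 26.1 CPM (log2 fold change -0.07, SE 0.12). The G2/M median moved to -0.16 without control 1, -0.38 without treated 1 and -0.15 without treated 2, and the list stayed called. PLK1 had -1.28 without treated 1 and -0.56 without treated 2, and MKI67 had -0.03 and -0.12 without controls 1 and 2 and -0.17 and 0.009 without treated libraries 1 and 2. With offsets for GC content and transcript length MKI67 had -0.014. Comparing control 1 with treated 1 against control 2 with treated 2, which mixes the groups, also called the histone list (median 0.20) and the G2/M list (median -0.14).

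**Figure D2:**
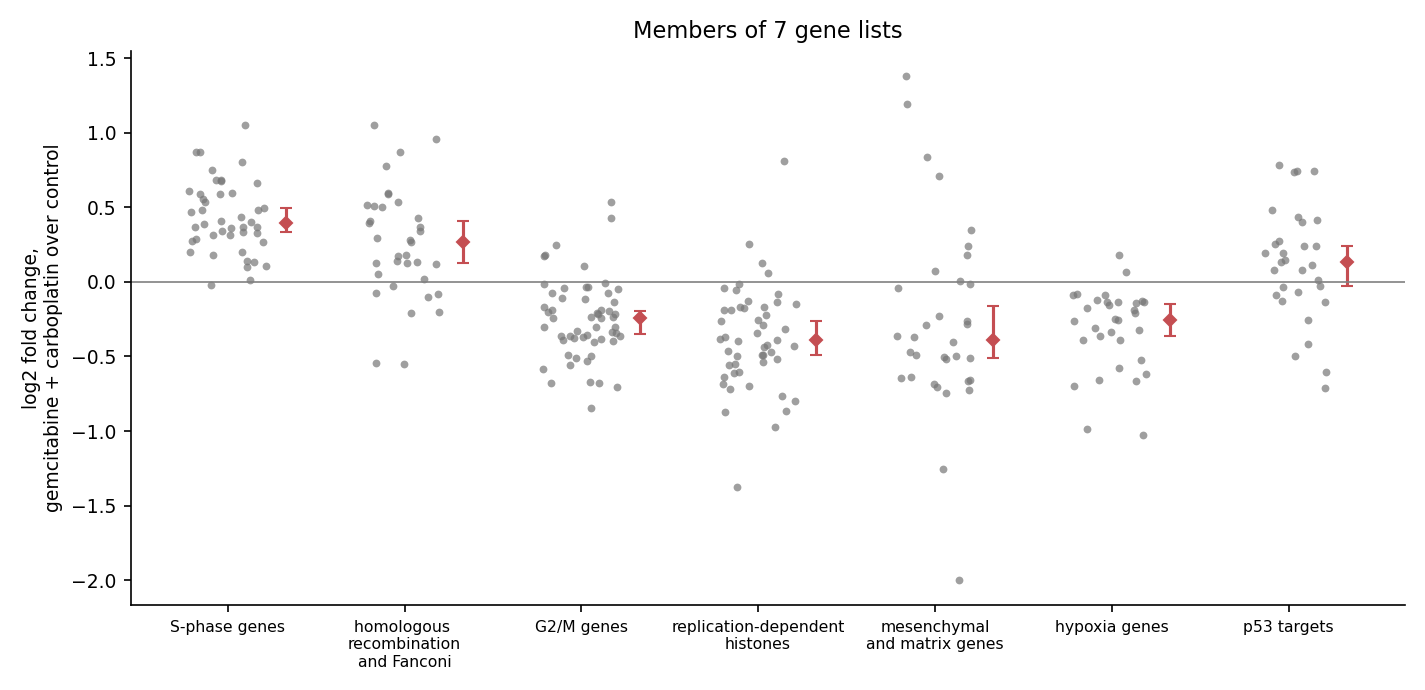
Log2 fold change of each tested member of 7 lists, treated over control, as grey points, with the median and its 95% bootstrap interval over genes as a red diamond and bar. The S-phase median is 0.40, the histone and matrix medians are both -0.39, and the interval of the p53 targets, -0.03 to 0.24, spans 0.

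Mesenchymal and matrix genes fell with a camera adjusted p of 1.93e-10 (adjusted p = 0.547 with an estimated correlation). Of 34 members, 25 were below 0, and 7 were lower when adjusted over the list alone. Over all genes edgeR called 0 of them, against 14 at an unadjusted p under 0.05, 6 by DESeq2 and 0 by limma-voom. The fibrillar collagen gene COL3A1 had 54.5 and 36.1 CPM in the controls and 8.09 and 17.4 CPM in the treated libraries (log2 fold change -2.00, SE 0.36). COL5A1 had a log2 fold change of -0.63 (SE 0.13), the fibronectin gene FN1 one of -0.74 (SE 0.15) and the intermediate filament gene VIM one of -0.28 (SE 0.10). Immediate early genes, many of which encode transcription factors, are induced by growth factors and stress. They fell by a median of 0.31 over 21 members (camera adjusted p = 4.27e-06, and 0.562 with an estimated correlation). Of these, 3 were lower when adjusted over the list alone. Adjusted over all genes, edgeR called 0 of them, against 8 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom. EGR1 had a log2 fold change of -0.98 (SE 0.25), FOSL1 one of -0.68 (SE 0.15) and JUN one of -0.45 (SE 0.10). Without control 2 the call of the immediate early list ended (camera adjusted p = 0.0650, median -0.22), and EGR1 had -0.63. With offsets for GC content and transcript length that list had a median of -0.20 and stayed called (camera adjusted p = 1.44e-03).

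Hypoxia and glycolysis genes were also called lower as groups, but the hypoxia levels of the groups overlapped. Relative to the control mean, hypoxia genes stood at -0.16 and 0.16 in controls 1 and 2 and at -0.43 and -0.08 in treated libraries 1 and 2. Comparing control 1 with treated 1 against control 2 with treated 2 gave hypoxia genes a median of 0.31. That was larger in size than the -0.25 between treated and control libraries. The hypoxia list had a median of -0.25 over 32 members, 30 of them below 0 (camera adjusted p = 1.58e-07; adjusted p = 0.736 with an estimated correlation), with 2 lower when adjusted over the list alone. With all genes counted, edgeR called 0 of them, against 6 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. The glucose transporter gene SLC2A1 had 240.0 ± 33.7 and 148 ± 16.1 CPM (log2 fold change -0.70, SE 0.15), PFKFB4 had a log2 fold change of -0.99 (SE 0.23) and NDRG1 one of -0.66 (SE 0.21). Glycolysis genes had a median of -0.19 over 19 members (camera adjusted p = 3.35e-04; adjusted p = 0.562 with an estimated correlation), with 1 lower when adjusted over the list alone. Over all genes edgeR called 0 of them, against 3 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. The enolase gene ENO1 had a log2 fold change of -0.48 (SE 0.10), PKM one of -0.37 (SE 0.10) and PFKP one of -0.35 (SE 0.12). The lists share 7 members, and the other 12 glycolysis genes had a median of -0.17 (95% bootstrap interval -0.36 to -0.04). The hypoxia call ended without control 2 (camera adjusted p = 0.394, median -0.10) and without treated 1 (camera adjusted p = 0.157, median -0.08), while the medians were -0.51 without control 1 and -0.45 without treated 2. The glycolysis call ended without control 2 (camera adjusted p = 0.0503, median -0.18) and without treated 1 (camera adjusted p = 0.201, median -0.12), and its median was -0.29 without treated 2. NDRG1 had -0.33 without control 2, and PFKP had -0.23 with offsets for GC content and transcript length.

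Lists of immune and inflammatory genes and of breast stem-like genes were called lower too. Relative to the control mean, interferon-stimulated genes stood at 0.07 in treated 2, above both controls. NF-kB and secretory inflammatory genes had a median of -0.25 over 26 members (camera adjusted p = 1.06e-03; adjusted p = 0.547 with an estimated correlation). The chemokine gene CCL5 had a log2 fold change of -1.14 (SE 0.30), IGFBP3 one of -0.93 (SE 0.28) and the NF-kB inhibitor gene NFKBIA one of -0.39 (SE 0.13). Antigen presentation genes had a median of -0.22 over 16 members (camera adjusted p = 0.0203; adjusted p = 0.562 with an estimated correlation). The class I genes HLA-B and HLA-C, whose similar sequences may share reads, had log2 fold changes of -0.28 (SE 0.11) and -0.28 (SE 0.12). Interferon-stimulated genes had a median of -0.14 over 40 members (camera adjusted p = 0.0285; adjusted p = 0.791 with an estimated correlation), with log2 fold changes of -0.71 (SE 0.23) for IFIT2, -0.67 (SE 0.22) for IFIT1 and -0.38 (SE 0.13) for IFIT3. Breast stem-like genes had a median of -0.25 over 13 members (camera adjusted p = 0.0174; adjusted p = 0.562 with an estimated correlation), with log2 fold changes of -0.59 (SE 0.19) for KLF4, -0.39 (SE 0.17) for NOTCH1 and -0.22 (SE 0.10) for CD44. In these 4 lists edgeR called 0 members over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 6, 2, 9 and 2 lower members in the order given and 2 higher in the NF-kB list, and DESeq2 and limma-voom called 0. The interferon median turned to 0.05 without treated 1 (camera adjusted p = 0.893), and that call also ended without control 2 (camera adjusted p = 0.261, median -0.14). The median was -0.25 without treated 2. The NF-kB median was -0.38 without treated 1. The antigen presentation call ended without control 1 (camera adjusted p = 0.0952, median -0.15), control 2 (camera adjusted p = 0.0548, median -0.28) or treated 1 (camera adjusted p = 0.216, median -0.15). The stem-like call ended without control 2 (camera adjusted p = 0.0503, median -0.27) or treated 1 (camera adjusted p = 0.168, median -0.17), with a median of -0.47 without treated 2. Without control 1 the values were -0.37 for IFIT1, -0.18 for HLA-C, -0.39 for KLF4 and -0.17 for NOTCH1. IFIT2 had -0.38 without control 2, and IGFBP3 had -0.54 without treated 1 and -1.42 without treated 2. With offsets for GC content and transcript length the antigen presentation call ended (camera adjusted p = 0.0886, median -0.14), and the values were -0.15 for HLA-B, -0.096 for HLA-C and -0.14 for NOTCH1. With a mean of at least 50 counts the antigen presentation (camera adjusted p = 0.0647), interferon (camera adjusted p = 0.106) and stem-like (camera adjusted p = 0.0536) calls ended.

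No single gene passed the test over all genes. Of 19161 genes tested, edgeR called 0 higher and 0 lower (smallest Benjamini-Hochberg adjusted p = 0.503), against 802 higher and 931 lower at an unadjusted p under 0.05, where chance alone gives 958 in all. DESeq2 called 26 higher and 87 lower, 14 of these 113 in genes with no count in either library of a group, and limma-voom called 0 higher and 1 lower. The groups did not overlap in 38.6% of genes, where chance gives 33.3%. In counts simulated from these libraries, edgeR recovered 1.49% of genes changed 1.5-fold, 14.9% of those changed 2-fold and 54.5% of those changed 4-fold. It called 1 of the 17381 unchanged genes that passed its filter. DESeq2, run without that filter, recovered 13.4%, 32.8% and 59.1% and called 62 unchanged genes. With 200 genes changed, false calls were therefore a large part of its calls there. The lower genes with the smallest p included SDK1, a cell adhesion gene (ENSG00000146555, chromosome 7, 3301448 to 4269000 on GRCh38). It had 52.5 ± 20.8 CPM in the controls and 11.6 ± 0.366 CPM in the treated libraries, a log2 fold change of -2.24 (SE 0.34). After H1-1 came LRMDA (ENSG00000148655, chromosome 10, 75431453 to 76560167) with a log2 fold change of -1.44 (SE 0.23) and the potassium channel gene KCNMA1 (ENSG00000156113, chromosome 10, 76869601 to 77638369) with -1.14 (SE 0.19). The higher genes with the smallest p were CLSPN (ENSG00000092853, chromosome 1, 35720218 to 35769967), EXO1 (ENSG00000174371, chromosome 1, 241847967 to 241895148), RRM2, the zinc exporter gene SLC30A1 with a log2 fold change of 0.62 (SE 0.12) and DDIAS with 1.00 (SE 0.20). These 9 genes had an edgeR adjusted p of 0.532, so none passed that test, while DESeq2 called all 9 (adjusted p from 1.34e-09 for SDK1 to 0.0226 for DDIAS). With a mean of at least 500 counts edgeR called SDK1 (adjusted p = 0.0305, over all its alternatives 1.34e-09 to 0.998). Leaving out 1 library moved the log2 fold change by over 1.5 times for 26 of the 58 named genes that are not markers of other cell types, with the values given beside each group.

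**Figure D3:**
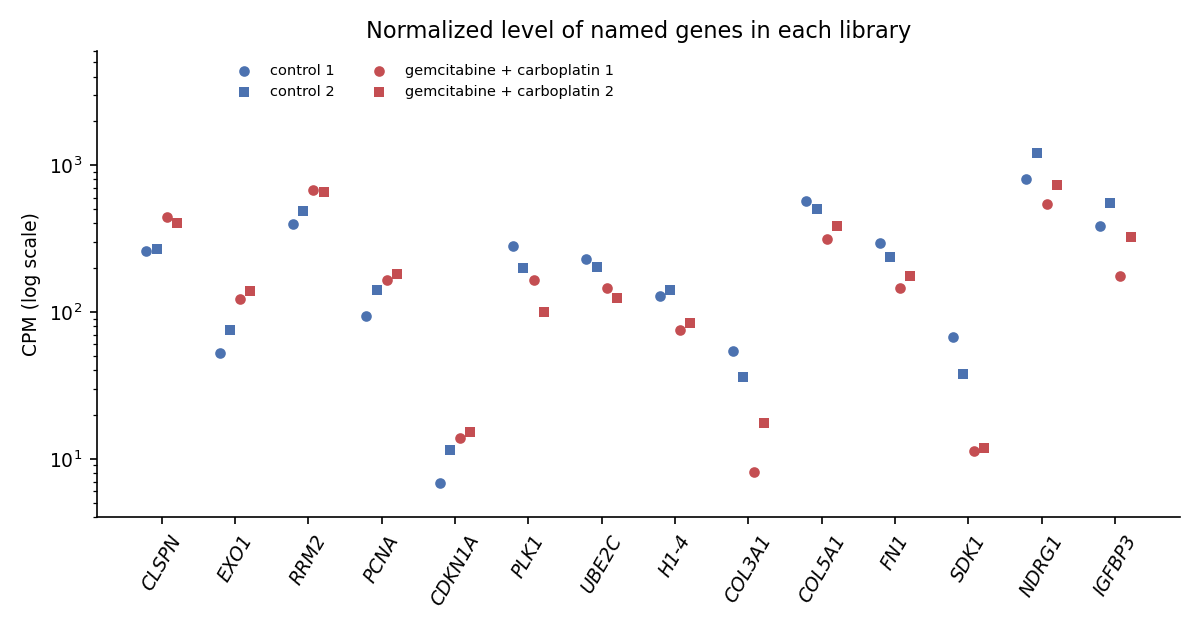
Normalized level of 14 named genes in each of the 4 libraries, in CPM on a log scale. EXO1 lies at 52.9 and 75.7 CPM in the controls and at 123 and 139 CPM in the treated libraries.

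Genes that handle gemcitabine rose as a list by a median of 0.16 over 24 members (camera adjusted p = 0.0467; adjusted p = 0.562 with an estimated correlation), with 1 higher when adjusted over the list alone. Adjusted over all genes, edgeR called 0 of them, against 1 higher and 1 lower at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. The large reductase subunit gene RRM1 had a log2 fold change of 0.37 (SE 0.16), the nucleoside transporter gene SLC29A1 one of 0.68 (SE 0.31) and the activating kinase gene DCK one of 0.15 (SE 0.15). The deaminase gene CDA was counted 0, 153, 23 and 50 times in controls 1 and 2 and treated libraries 1 and 2, so its direction cannot be read. The list's call ended in each of the 4 fits that left out a library, with camera adjusted p of 0.325 without control 1, 0.0503 without control 2, 0.157 without treated 1 and 0.147 without treated 2, and medians of 0.14, 0.22, 0.13 and 0.10. It also ended with no count filter (camera adjusted p = 0.107) and with a mean of at least 500 counts (camera adjusted p = 0.0544). Its 21 members outside the S-phase list had a median of 0.12 (95% bootstrap interval -0.04 to 0.24). Genes of platinum transport and thiol detoxification were not called (median -0.01 over 24, camera adjusted p = 0.741). The copper transporter gene SLC31A1 had a log2 fold change of 0.35 (SE 0.21), and ATP7B one of -0.26 (SE 0.52). Without control 1 the values were 0.13 for RRM1, 0.38 for SLC29A1, 0.04 for SLC31A1 and 0.97 for ATP7B. Without control 2 they were 0.60 for RRM1, 0.65 for SLC31A1 and -0.66 for ATP7B, while ATP7B had -0.16 without treated 1 and SLC29A1 had 0.45 without treated 2. CDA had -2.11 and 8.60 without controls 1 and 2 and 0.39 and -1.58 without treated libraries 1 and 2. With offsets for GC content and transcript length DCK had 0.017. ATP7B had -0.11 with limma-voom, -0.059 with DESeq2, -0.050 with the earlier quasi-likelihood method and -0.0063 after thinning, and CDA had -0.85 with DESeq2, -0.84 with the earlier method, -1.13 after thinning and 3.51 with limma-voom.

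The p53 target list was not called (median 0.13 over 31, camera adjusted p = 0.558). Its median was 0.018 without control 1, 0.20 without control 2, 0.046 without treated 1 and 0.16 without treated 2. CDKN1A, the cell cycle inhibitor, had 9.17 ± 3.24 CPM in the controls and 14.5 ± 0.914 CPM in the treated libraries (log2 fold change 0.74, SE 0.33). MDM2 had a log2 fold change of -0.07 (SE 0.13) and GDF15 one of -0.71 (SE 0.31). ATM/ATR checkpoint genes had a median of 0.07 (camera adjusted p = 0.558), with 0.02 (SE 0.16) for CHEK1, and BRCA1 had a log2 fold change of 0.27 (SE 0.15). Nucleotide excision repair genes had a median of 0.12 (camera adjusted p = 0.123; 0.029 without control 1 and 0.19 without treated 1), pro-apoptotic genes -0.06 (camera adjusted p = 0.908) and anti-apoptotic genes 0.00 (camera adjusted p = 0.908). None of these lists passed the threshold, and for pro-apoptotic genes and for platinum transport the test leaned up while the median lay below 0. Without control 1 the values were 0.32 for CDKN1A, -0.22 for GDF15 and 0.13 for CHEK1. CHEK1 had -0.06 without control 2, -0.0058 without treated 1 and 0.036 without treated 2, and MDM2 had -0.16 without treated 1 and -0.0042 without treated 2. CHEK1 had -0.072 with offsets for GC content and transcript length, 0.0066 with no count filter, 0.037 with a mean of at least 50 counts and 0.033 after thinning.

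Among the other programs, lysosome and autophagy genes had a median of -0.18 (camera adjusted p = 0.0545), ribosome biogenesis 0.09 (camera adjusted p = 0.0978), epithelial genes -0.17 (camera adjusted p = 0.137), cytosolic ribosomal proteins 0.06 (camera adjusted p = 0.354) and nuclear oxidative phosphorylation genes 0.07 (camera adjusted p = 0.558). Proteasome genes had a median of 0.05 (camera adjusted p = 0.693), NRF2 targets 0.01 (camera adjusted p = 0.843) and heat shock genes 0.07 (camera adjusted p = 0.857). The integrated stress response and unfolded protein response list had a median of -0.01 and cholesterol biosynthesis 0.01, both with a camera adjusted p of 0.908, and multidrug transporters had a median of -0.02 (camera adjusted p = 0.960). The test leaned down for cholesterol biosynthesis and up for multidrug transporters, against the sign of their medians. None of these 11 lists was called with all 4 libraries. Cytosolic ribosomal proteins were called higher without control 2 (camera adjusted p = 0.0214, median 0.10) or treated 1 (camera adjusted p = 0.00210, median 0.10). Ribosome biogenesis was called higher without control 1 (camera adjusted p = 0.00583, median 0.12), and epithelial genes lower without treated 2 (camera adjusted p = 0.0150, median -0.26). The epithelial median was -0.075 without control 1 and 0.0053 without treated 1. The lysosome and autophagy median was -0.047 without control 1 and -0.11 without treated 2, that of ribosome biogenesis 0.16 without treated 1 and that of nuclear oxidative phosphorylation genes 0.024 without control 1.

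Of the 3 lists on RNA quality, 2 were called higher, but their levels overlapped between the groups. Relative to the control mean, structural RNAs stood at -0.2586 and 0.2586 in controls 1 and 2 and at 0.2582 and 0.9578 in treated libraries 1 and 2. In the same order, mitochondrial mRNAs stood at -0.17, 0.17, 0.32 and 0.02. Structural noncoding RNAs rose by a median of 0.72 over 12 members (camera adjusted p = 6.11e-04; adjusted p = 0.663 with an estimated correlation), with 2 higher when adjusted over the list alone. With all genes counted, edgeR called 0 of them, against 2 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. Mitochondrially encoded mRNAs rose by a median of 0.22 over 13 (camera adjusted p = 1.05e-03; adjusted p = 0.746 with an estimated correlation). Of these, edgeR called 0 adjusted over the list alone or over all genes, 1 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The mitochondrial ribosomal RNAs MT-RNR2 and MT-RNR1 had log2 fold changes of 0.69 (SE 0.17) and 0.74 (SE 0.20), and the spliceosomal RNA RNU5A-1 had 1.08 (SE 0.47). MT-ATP8, MT-ND4L and MT-CO3 had 0.68 (SE 0.25), 0.31 (SE 0.14) and 0.33 (SE 0.15). Mitochondrial mRNA took 4.30% and 5.22% of counts in the controls and 5.82% and 4.87% in the treated libraries, and mitochondrial ribosomal RNA took 0.345% and 0.478% against 0.587% and 0.771%. The structural RNA call ended without control 1 (camera adjusted p = 0.0798, median 0.22) or treated 2 (camera adjusted p = 0.137, median 0.28). The mitochondrial call ended without control 1 (camera adjusted p = 0.454, median 0.04) or treated 1 (camera adjusted p = 0.216, median 0.01), with a median of 0.34 without control 2. Without control 1 the values were 0.46 for MT-RNR2, 0.69 for RNU5A-1, 0.27 for MT-ATP8, 0.10 for MT-ND4L and 0.12 for MT-CO3. Without control 2 they were 1.20 for MT-ATP8, 0.53 for MT-ND4L and 0.56 for MT-CO3. RNU5A-1 had 1.74 and MT-CO3 had 0.18 without treated 1, and RNU5A-1 had 0.32 and MT-RNR1 had 0.41 without treated 2. With offsets for GC content and transcript length the medians were 0.42 for structural RNAs and 0.12 for mitochondrial mRNAs, both still called, with 0.57 for RNU5A-1, 0.39 for MT-ATP8 and 0.099 for MT-ND4L. The split of control 1 with treated 2 against control 2 with treated 1 gave mitochondrial mRNAs a median of 0.29, above the 0.22 of the treatment split. Nuclear-retained long RNAs were not called (median -0.15, camera adjusted p = 0.688; -0.035 without control 1 and -0.080 without treated 1).

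Markers of other cell types were mostly low, with a median of 1.44 CPM over the 64 tested, and none of their lists was called with all 4 libraries. They are human genes while the host is chicken, so their counts may come from the tumor cells and do not measure host content. The camera adjusted p was 0.385 for embryonic mesenchyme and cartilage (median -0.09), 0.654 for neural crest and glia (median 0.12, with the test leaning down), 0.688 for endothelial cells (median -0.51), 0.688 for skeletal and cardiac muscle (median 1.20), 0.742 for leukocytes (median 0.07) and 0.908 for neurons and neural tube (median 0.06). Muscle genes were called higher without treated 2 (camera adjusted p = 0.0336, median 1.87). The neural crest median was -0.43 without control 1, 0.22 without control 2 and -0.0068 without treated 1. The mesenchyme median was 0.12 without control 2 and -0.17 without treated 2. Erythroid markers had only 3 tested members and were not tested as a list. The members with the highest mean CPM were SOX9 (191 ± 2.51 and 170 ± 16.5 CPM in control and treated libraries) and TBX18 (89.6 ± 12.4 and 82.7 ± 3.78 CPM) for embryonic mesenchyme. They were MITF (22.3 ± 3.35 and 32.9 ± 0.377 CPM) and TFAP2A (13.1 ± 3.76 and 10.5 ± 4.37 CPM) for neural crest, and FLT4 (28.2 ± 13.7 and 26.5 ± 2.03 CPM) and EGFL7 (18.1 ± 0.370 and 19.8 ± 2.12 CPM) for endothelium. For neurons they were MAP2 (22.5 ± 1.44 and 19.9 ± 0.647 CPM) and NEFL (13.1 and 28.9 CPM in the controls, 19.6 ± 1.94 CPM in the treated libraries). The leukocyte genes CD14 and CD74, the muscle genes NEB and DES and the erythroid genes SPTB and TAL1 had means under 5 CPM in both groups.

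No 2 libraries held the same counts within counting error. By an exact binomial test adjusted by Benjamini-Hochberg, which covers counting error only and depends on depth, 70.5% of 25886 genes differed between the controls and 53.7% of 27138 between the treated libraries. Between a control and a treated library the share was 56.5% to 72.6%. Control 1 stood apart, with a Pearson correlation of log2 CPM across genes of 0.906 with control 2, 0.910 with treated 1 and 0.900 with treated 2, while the other pairs gave 0.934 to 0.945. Genes are not independent replicates, so these correlations describe the libraries only. Control 1 had 102 genes at 0 counts whose mean in the other libraries was at least 1 CPM, against 49, 38 and 63 in control 2 and treated libraries 1 and 2.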

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

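The offsets for GC content and transcript length and the filter at a mean of at least 500 counts were chosen after seeing the data, and all other alternatives were fixed before the data were examined. DESeq2 called 26 genes higher and 87 lower. The genes lower numbered 1 with limma-voom, 1 with a mean of at least 50 counts and 2 with a mean of at least 500 counts, and edgeR called 0 higher and 0 lower under each other setting. The lists numbered 3 higher without mitochondrial and structural RNAs, a setting that removes 2 of the higher lists, and 0 higher and 0 lower with an estimated correlation or with fry. Leaving out each library gave 3 to 5 lists higher (3 without control 1) and 4 to 11 lower (4 without control 2, 5 without treated 1). The lists of S-phase, homologous recombination, G2/M, histone, NF-kB and matrix genes stayed called in all 4 of these fits, and in 13 of the 15 alternatives run on lists, the exceptions being the estimated correlation and fry. The offsets ended the antigen presentation call (adjusted p = 0.0886, median -0.136 against -0.216, adjusted p over all its alternatives 0.00738 to 0.562). A mean of at least 50 counts also ended that call (0.0647) and those of interferon-stimulated (0.106, over all its alternatives 2.45e-06 to 0.893) and stem-like genes (0.0536, over all its alternatives 0.00136 to 0.562), and left 7 lists lower. No count filter (0.107) and a mean of at least 500 counts (0.0544) ended the gemcitabine call (over all its alternatives 0.0157 to 0.562). Whether replicate numbers pair the libraries cannot be settled here. The correlation of same-number deviations was -0.0087 across all genes and 0.079 across genes with a mean of at least 500 counts. Splitting the libraries by replicate number called 6 lists, and the other split that mixed the groups called 2. With the number as a block, edgeR called 0 genes higher and 0 lower and camera 5 lists higher and 11 lower, the added one being lysosome and autophagy genes (adjusted p = 0.0485, over all its alternatives 0.0137 to 0.712). That list was also called with no count filter (0.0137) and after thinning (0.0482), ribosome biogenesis with a mean of at least 50 counts (adjusted p = 0.0439, over all its alternatives 0.00583 to 0.745) and epithelial genes with a mean of at least 500 counts (adjusted p = 0.00889, over all its alternatives up to 0.844).

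Of the values of named genes under the alternatives, 887 kept direction and side of the threshold, 25 passed it and 8 turned. Of those of lists, 477 kept both, 55 lost the call, 10 gained one and 35 turned. Only 1 of the turned values belonged to a result past the threshold, that of interferon-stimulated genes. For all of these the cause was not tested. For lists the direction is that of the test and the value is the median. The values were -0.072 for CHEK1, 0.059 for the stress response list and 0.0099 for proteasome genes with the offsets, and 3.51 for CDA with limma-voom. With a mean of at least 50 counts they were 0.013 for anti-apoptotic genes, 0.009 for the stress response, 0.0305 for cholesterol biosynthesis, -0.0034 for multidrug transporters and -0.13 for leukocytes. With a mean of at least 500 counts they were -0.0056 for anti-apoptotic genes, -0.0255 for the stress response and -0.022 for multidrug transporters. With no count filter they were -0.089 for pro-apoptotic genes, 0.052 for heat shock genes, -0.033 for multidrug transporters and 0.1025 for endothelial cells. After thinning they were -0.12 for leukocytes and -0.102 for neurons.

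Leaving out each library gave ranges of -0.17 to 0.009 for MKI67, -2.11 to 8.595 for CDA, -0.66 to 0.97 for ATP7B and -0.064 to 0.13 for CHEK1. For lists the ranges were 0.022 to 0.043 for ATM/ATR checkpoint, -0.047 to 0.11 for platinum transport, -0.14 to 0.022 for pro-apoptotic, -0.12 to 0.045 for anti-apoptotic and -0.25 to 0.049 for interferon-stimulated genes. They were -0.063 to 0.013 for the stress response, -0.0715 to 0.0403 for cholesterol biosynthesis, -0.0096 to 0.10 for ribosomal proteins, 0.024 to 0.11 for heat shock, -0.0052 to 0.059 for proteasome, -0.063 to 0.024 for NRF2 targets and -0.15 to 0.33 for multidrug transporters. For other cell types they were -0.25 to 0.19 for endothelial cells, -0.049 to 1.59 for leukocytes, -1.64 to 2.96 for muscle and -0.12 to 0.58 for neurons. The ranges of the other lists not called were 0.018 to 0.20 for p53 targets, 0.029 to 0.19 for nucleotide excision repair, -0.22 to -0.047 for lysosome and autophagy, -0.26 to 0.0053 for epithelial genes, 0.069 to 0.16 for ribosome biogenesis, 0.024 to 0.067 for nuclear oxidative phosphorylation, -0.20 to -0.035 for nuclear-retained RNAs, -0.43 to 0.22 for neural crest and -0.17 to 0.12 for embryonic mesenchyme. With the offsets the medians were 0.13 for pro-apoptotic genes, 0.060 for nucleotide excision repair and -0.089 for lysosome and autophagy. As to depth, after thinning to the smallest total, 30278292 counts, camera called 5 lists higher and 11 lower, and in simulated data of the same depths edgeR recovered 54.5% of 4-fold and 14.9% of 2-fold changes.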

Other observations

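The S-phase test without control 1, the tests of the other histone genes and of host-cell markers, the comparison with other splits and the test of treatment on long genes were chosen only after the result was seen, and so were the pattern of long genes and its limits, noticed from the names of the lowest genes.

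Protein-coding genes with a genomic span over 300 kb were lower after gemcitabine and carboplatin. Among those with a mean of at least 50 counts, 532 had such a span and a median log2 change of -0.33 (95% bootstrap interval over genes -0.37 to -0.27), with 79.5% below 0. At an unadjusted p under 0.05, 130 of them were lower and 3 higher, and DESeq2 called 20 lower and 0 higher, while edgeR called 0. The medians were -0.06 under 10 kb (2281 genes), -0.01 from 10 to 30 kb (3499 genes), 0.04 from 30 to 100 kb (4236 genes) and -0.03 from 100 to 300 kb (2121 genes). Across all 12669 genes the Spearman correlation of span and change was -0.00744, and no median below 300 kb came near that of the longest genes. Relative to the control mean, the medians of the longest genes were 0.01 and -0.01 in the controls and -0.30 and -0.36 in the treated libraries. The cell adhesion gene SDK1 (log2 fold change -2.24, SE 0.34), LRMDA (-1.44, SE 0.23), the potassium channel gene KCNMA1 (-1.14, SE 0.19), the semaphorin gene SEMA5A (-1.32, SE 0.24) and the glypican gene GPC6 (-0.92, SE 0.18) were examples, chosen after their values were seen. Without the named genes and those DESeq2 called, the median of the 511 left was -0.31. Removing so few genes could hardly move the median, so this value does not offset how the pattern was found. Of the 532, 3 belonged to a called list.

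The difference between genes over 300 kb and under 30 kb was -0.302 (95% interval -0.348 to -0.249). It was -0.338 with offsets for GC content and transcript length and -0.319 without control 1, which argues against either as the whole cause. It stayed between -0.34 and -0.26 on leaving out each library. RNA from unspliced transcripts cannot be told apart, since 49 sense intronic and overlapping genes had a median of -0.0692 with a wide interval (-0.701 to 0.429). The difference was -0.0058 and 0.00 in the other 2 splits of the 4 libraries, and 3 splits are too few for a share under 0.05. Treatment as the cause therefore stays open.

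S-phase genes were higher (median 0.40) while replication-dependent histone genes were lower (median -0.39). The S-phase median was 0.332 with GC and length offsets, 0.388 after thinning and 0.317 without control 1, and the list stayed called each time, which argues against these as the whole cause. The histone median was -0.372 with the offsets. It was 0.20 in the split of control 1 with treated 1 against control 2 with treated 2, which also called the histone list. Whether the loss was limited to replication-dependent histones cannot be told apart, since 11 other histone genes had a median of -0.121 (interval -0.490 to 0.064) and went both ways, among them H1-10 (log2 fold change -0.85, SE 0.15) and H2AZ1 (0.19, SE 0.12). No biological explanation was tested for this pattern.

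Mesenchymal and matrix genes were lower (median -0.39). The median was -0.327 with GC and length offsets, and -0.421 (interval -0.518 to -0.225) relative to genes of the same span over 30 genes, which argues against both as the whole cause. Fewer host cells in the treated grafts cannot be told apart from a change in the tumor cells. Only 8 markers of other cell types outside the list reached 10 CPM (median -0.127, interval -0.196 to 0.117), below the 10 set for the test. They are also human genes while the host is chicken, so their counts may come from the tumor cells. SOX9, the highest of them, is also in the breast stem-like list. More markers of this kind would therefore not settle the question.

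In the treatment split camera called 15 lists, and the highest count in the other splits was 6. A count of 15 lists was thus reached in 1 of the 3 splits, the treatment split, and 3 splits are too few for a share under 0.05. DESeq2 called 113 genes in the treatment split and 6 and 11 in the others. The split of control 1 with treated 1 against control 2 with treated 2 called hypoxia (median 0.31), histone (0.20), G2/M (-0.14), interferon-stimulated (0.13) and cytosolic ribosomal protein genes (0.12) and structural noncoding RNAs (0.56). The split of control 1 with treated 2 against control 2 with treated 1 called interferon-stimulated genes (-0.13) and mitochondrially encoded mRNAs (0.29). These lists therefore also differed between libraries of the same group.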
